A study of Caenorhabditis elegans with 2 samples.

How the data were processed

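The data are peak lists from a ChIP-seq experiment on whole worms, with 1 group of 2 biological replicates and a control common to both, per the labels and the text deposited with the lists. The authors deposited 4 lists for each of 2 genome builds, ce10 and ce11: 1 per replicate, 1 from pooled reads and 1 optimal list thresholded on the irreproducible discovery rate (IDR), which uses the ranks in both replicates. Peaks were therefore called both per replicate and on pooled reads. The thresholded list was derived from the replicate and pooled lists, per the notes deposited with them. The aligner, peak caller, versions, scaling, IDR threshold and handling of reads that match several places were not given in the sources used here. Each peak carries a signal value and a −log10 q value, both deposited by the authors. The −log10 q was constant in the thresholded list and was not used for ranking, so peaks were ranked by the deposited signal. Sequencing depth is unknown, no read counts were used, and intervals on shares of peaks are exact binomial ones that cover counting error only.

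Samples were named by the replicate number in the labels. Coordinates are in ce11 and 1-based. Genes were taken from the RefSeq annotation of the same assembly, and no coordinate was converted between builds. The ce10 lists served for counts and for replicate matching only. Peak summits came from the summit offset in the lists. A peak was placed, in this order, on mitochondrial DNA, within 200 bp of a tRNA, snoRNA, spliced leader, snRNA, rRNA or miRNA gene, in a promoter window, in an exon, in an intron or between genes.

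Replicates were compared by the share of the 549 strongest replicate 1 peaks overlapped by at least 1 bp by the 549 strongest replicate 2 peaks, with 1000 circular shifts of replicate 2 along each chromosome and a one-sided p. Promoter share and the 7 non-coding RNA classes used 1000 circular shifts and two-sided p-values. The 17 gene lists used Fisher's exact test, and chromosomes and the central 50% of autosomes exact binomial tests. Signal was compared by a permutation test of 100000 resamples, motifs by exact McNemar tests in windows of 50 bp to each side of the summit and 500 bp away, and GC content by sign-flip permutation. Families of tests were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and neighbouring genes that share a peak are not independent in Fisher's test.

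These designs, the gene lists, the motifs and most alternatives were fixed before the data were examined. The 17 mitochondrial peaks had not been foreseen: they were left out of the tests of nuclear places (promoters, RNA classes, gene lists and chromosomes) and kept in replicate matching, signal and sequence, and the reverse handling was added as an alternative for promoter share, replicate matching, signal and sequence. Alternatives without peaks near small RNA genes were also added after exploratory runs had shown where the peaks lay. Genes named in the Results are those with the start nearest to each of the 25 strongest peaks, up to 4 per list or class by signal, and dao-5 and the nuclear rRNA genes. Further small RNA genes named under other observations were picked after the peaks were seen. Of the 25 strongest, the 17 mitochondrial ones are described together.

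The class, gene list, chromosome, promoter, motif, GC content, signal and replicate tests were tested on simulated lists of 532 peaks or values, and the test of the central part of autosomes was not. In 20 random lists the class, gene list and chromosome tests made a false call in 0. Positions in these lists were drawn independently and in proportion to chromosome length, so false calls with clustered peaks were not measured. With 40 peaks planted at tRNA genes 44 were counted near such genes, and with 15 planted at chemoreceptor starts 23 genes had a summit, since neighbours and chance peaks add to both. With 60 summits planted on a motif 72 carried it, and lists made to share 50% of peaks gave 50.4%. With 150 summits planted at gene starts 239 lay in promoter windows (circular-shift permutation p = 0.0020), against 0.515 for a random list. Summits placed on GC-rich windows gave a permutation p of 1e-05 for GC content and a random list 0.423, and doubled signals gave 1e-05 and unchanged ones 0.833. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used with a fixed seed.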

Results

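The binding of DAO-5 to the genome of Caenorhabditis elegans was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody to GFP. DAO-5 is the worm relative of Nopp140, a protein of the nucleolus, the nuclear compartment in which ribosomal RNA is made. The worms were L4 larvae or young adult hermaphrodites of a strain that carries DAO-5 fused to GFP and FLAG, and whole animals were used. The study held 1 group of 2 biological replicates, so the questions it answers are where peaks lay and how far the replicates matched. Sequencing depth was not given in the sources used here. The lists held 23091 peaks for replicate 1, 21273 for replicate 2 and 16687 for the pooled reads in ce11, and the authors' thresholded list held 549. Those 549 were the strongest pooled peaks without exception. A listed peak therefore need not rank high in each replicate: the peak at mir-80 ranked 76 in replicate 2 and 13212 in replicate 1. Peak signal is the authors' value and was used here only to rank and describe peaks within a list.

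Replicates shared many of their strongest peaks. Of the 549 strongest peaks of replicate 1, 298 (54.3%, exact 95% interval 50.01 to 58.51%) were overlapped by at least 1 bp by the 549 strongest of replicate 2. Circular shifts of the replicate 2 peaks gave 2.88% on average and at most 4.37%, for a one-sided p of 0.0010, the smallest that 1000 shifts can give. Among the 65 peaks placed at snoRNA genes, 54 (83.1%) ranked within the strongest 549 in both replicates. So did 90 of 175 tRNA peaks (51.4%) and 56 of 139 peaks in protein-coding promoters away from small RNA genes (40.3%). Median signals in the thresholded list ran in the same order, at 82.3, 65.3 and 61.1, so place and strength are not separated here. Across the 532 nuclear peaks the signals in the replicate lists had a Spearman coefficient of 0.242. That value is across peaks of a list selected on pooled signal, and peaks are not independent replicates.

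**Figure D1:**
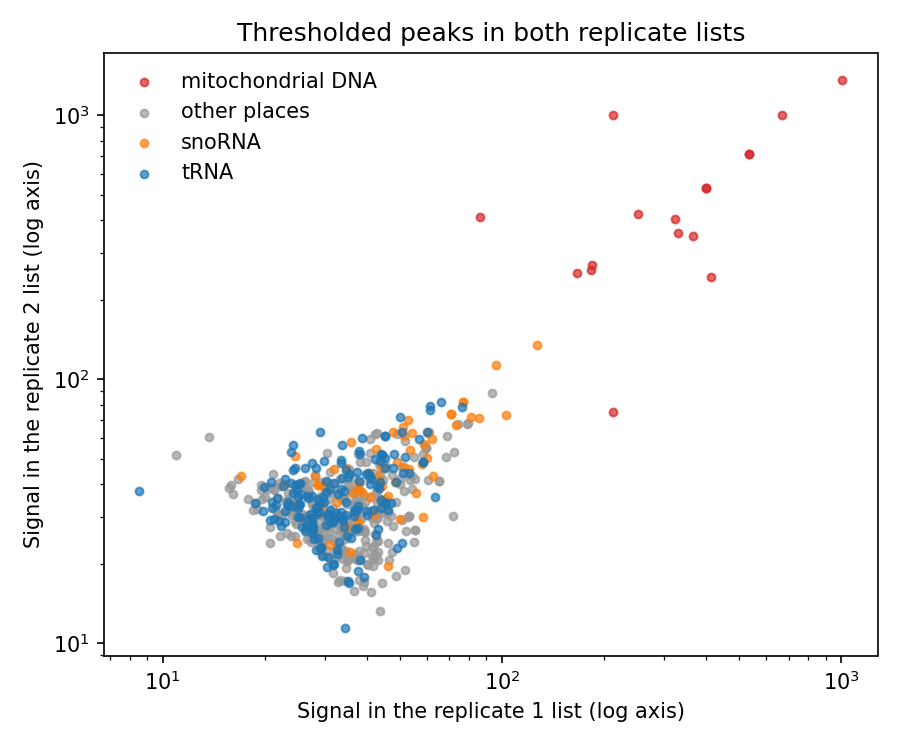
Signal of each of the 549 thresholded peaks in the replicate 1 list (horizontal, log axis) and in the replicate 2 list (vertical, log axis), taking the strongest overlapping peak, with 1 point per peak coloured by place. Most of the 17 mitochondrial peaks stand at the upper right, and the median signal in the pooled reads was 82.3 for snoRNA peaks and 65.3 for tRNA peaks.

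Genes for small structured RNAs were the most frequent place of peaks. Transfer RNA genes, which RNA polymerase III transcribes, lay within 200 bp of 175 of the 532 nuclear peaks (32.9%), against 3.02 in the circular shifts, a 57.99-fold excess, and 204 of 612 tRNA genes (33.3%) were reached. Genes of snoRNAs, which guide the modification of ribosomal RNA in the nucleolus, lay near 66 peaks against 1.66 in shifts, and 65 of 346 were reached. The snRNA class, which here includes the spliced leader genes, had 10 peaks against 0.504, and the spliced leader RNA genes, whose RNA is joined to the start of many worm messages, had 4 against 0.123. Of 30 spliced leader genes 4 were reached, all of them sls-2 genes, so that excess rests on sls-2 genes only. Each of these 4 classes had an adjusted p of 0.0035, which is the smallest p of 1000 two-sided shifts after Benjamini-Hochberg adjustment over 7 classes. The size of the excess depended on the distance allowed: for tRNA it was 94.2-fold with overlap only and 23.2-fold within 1000 bp, and for snoRNA 63.2-fold and 17.4-fold. How reads shared between copies bear on the tRNA count is not known. Of the 612 tRNA genes, 592 share a stretch of 30 bases with another place in the genome.

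The strongest nuclear peak lay at the snoRNA genes C51F7.4 and C51F7.3 on chromosome V (12303513 to 12303706 in ce11, within an intron), with a signal of 257.9 in the pooled list, 126.8 in replicate 1 and 135.2 in replicate 2. Peaks at ZK994.7 (signal 208.3) and T03F7.8 (173.6) also lay in introns of protein-coding genes on V. Outside protein-coding genes were those at W03C9.9 on II (159.1), T19B4.8 on I (156.2) and Y75B12B.12 on V (153.4), all snoRNA genes. At rpr-1, the gene of the RNA of RNase P, which trims tRNA precursors, the signal was 178.2. The leading tRNA peaks were on X, at the leucine tRNA gene C04A11.t1 (158.4), at the neighbouring glycine and glutamate tRNA genes M02F4.t1 and M02F4.t2 (148.2 for 1 shared peak) and at the alanine tRNA gene F15G9.t1 (141.6). Spliced leader genes sls-2.4 (125.1), sls-2.1 (121.2), sls-2.2 (108.2) and sls-2.8 (58.5) had 1 peak each, and the next snRNA gene was W05B2.8 (108.2).

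**Figure D2:**
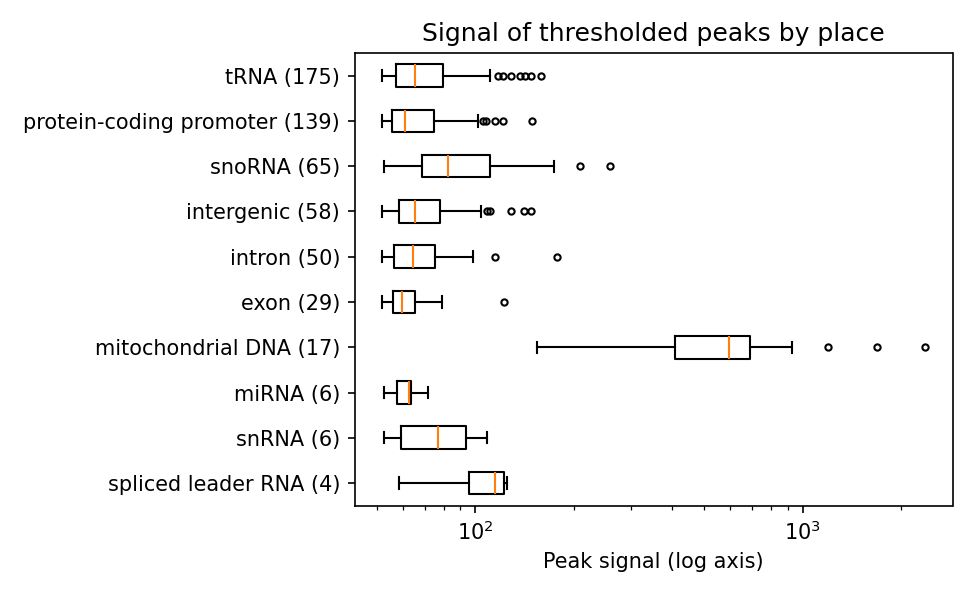
Peak signal (horizontal, log axis) of the 549 thresholded peaks by place, with the number of peaks in parentheses. Boxes span the quartiles with the median as a line, whiskers reach the farthest values near the box and points are values beyond. The median was 82.3 at snoRNA genes, 65.3 at tRNA genes and 594.2 on mitochondrial DNA.

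MicroRNA and piRNA genes gave smaller departures. Peaks near miRNA genes numbered 6 against 1.19 in shifts (circular-shift permutation test, adjusted p = 0.0056), at genes that included mir-4936, mir-80, mir-229 and mir-2214, all on III. At mir-80 the replicates differed, with a signal of 51.5 in replicate 2 and 10.9 in replicate 1. Genes of piRNAs, which are clustered on IV, lay near 10 peaks against 20.4 in shifts (circular-shift permutation test, adjusted p = 0.021), among them 21ur-5229, 21ur-10291, 21ur-5629 and 21ur-14981. Neither call held throughout. Among the 274 strongest peaks both ended, at 1.67-fold for miRNA (permutation, adjusted p = 1) and 0.431-fold for piRNA (permutation, adjusted p = 0.112). With overlap only the piRNA ratio was 0.197-fold and called (permutation, adjusted p = 0.0028), and the miRNA ratio was 4.22-fold and not called (permutation, adjusted p = 0.0932). The strongest peaks of replicate 2 alone (without replicate 1) gave 3.45-fold for miRNA (permutation, adjusted p = 0.0676), and those of replicate 1 alone (without replicate 2) gave 0.606-fold for piRNA (permutation, adjusted p = 0.0536).

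No thresholded peak lay on any of the 20 annotated nuclear rRNA genes or at dao-5. The rRNA genes were rrn-1.1, rrn-1.2, rrn-2.1 and rrn-3.1 at the end of chromosome I, and 16 genes of 5S rRNA, rrn-4.1 to rrn-4.16. Only rrn-4.15 on V (17428879 to 17428996) was overlapped in other lists, by 1 peak in the pooled list and 1 in replicate 1. The gene dao-5 lies on I from 10187546 to 10190896 on the minus strand. The nearest pooled peaks ended 2413 bp to its left and began 35890 bp to its right. In the replicate lists dao-5 lay in a stretch of 39142 bp (10182724 to 10221865) without a peak from either replicate. Of 30631 such gaps 18 (0.059%), the one at dao-5 included, were at least as long, and the median gap was 1454 bp. The cause of this gap was not tested, so the missing peak at dao-5 does not measure a lack of binding. Whether reads from repeated genes such as rDNA were kept was not given in the sources used here, so a missing peak there does not measure a lack of binding.

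Promoters of protein-coding genes held more summits than shifted positions did. Summits lay within 1000 bp upstream to 200 bp downstream of a gene start for 199 of 532 nuclear peaks (37.4%, exact 95% interval 33.3 to 41.7%), against 20.6% in circular shifts and 27.3% in the highest shift, with a two-sided p of 0.0020, the smallest possible. The 1.817-fold excess was 2.78-fold in the narrower window of 500 bp upstream. Those windows belonged to 243 of 19971 nuclear protein-coding genes.

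Among 17 gene lists fixed in advance, 3 passed Fisher's exact test after Benjamini-Hochberg adjustment. Cytosolic ribosomal protein genes had a summit in 9 of 78 cases (11.5%) against 1.18% of other genes, an odds ratio of 10.96 (Fisher's exact test, adjusted p = 7.5e-06). They included rpl-3 (signal 149.4), rpl-15 (93.3), rpl-18A (91.6) and rpl-35 (86.96). Heat shock protein and chaperone genes had 7 of 61 (odds ratio 10.8, exact test, adjusted p = 5.1e-05), with the mitochondrial chaperonin hsp-60 (76.2), the DnaJ genes dnj-29 (61.1) and dnj-13 (59.9) and the chaperonin subunit cct-7 (57.7). Without replicate 2 the odds ratio was 6.22 (exact test, adjusted p = 0.0285), and among the 274 strongest peaks the call was lost (odds ratio 3.06, exact test, adjusted p = 0.537). Chemoreceptor genes, which act in sensory neurons, had 1 of 1275 (odds ratio 0.0599, exact test, adjusted p = 3.2e-05). Without replicate 1 the odds ratio was 0.123 and without replicate 2 it was 0.195, both past the threshold in the exact test, while among the 274 strongest peaks the call was lost (odds ratio 0.135, exact test, adjusted p = 0.0863). The 1 was sre-23, whose peak lay at a snoRNA gene, and with circular shifts in place of Fisher's exact test this list was not called (adjusted p = 0.333).

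The other 14 lists did not pass. Intestinal genes had 2 of 19, act-5 and the yolk protein gene vit-2 (exact test, adjusted p = 0.0935), and nucleolar and ribosome biogenesis genes had 2 of 31, pro-1 and the exoribonuclease gene xrn-2 (adjusted p = 0.185). The signal at xrn-2 was 15.7 in replicate 1 and 38.6 in replicate 2. Core histones had 2 of 72, his-37 and his-59 (odds ratio 2.33, exact test, adjusted p = 0.619), with odds ratios of 3.64 without replicate 1 and 1.23 without replicate 2, neither called. Lists with 1 gene each were translation factors (iff-2), aminoacyl-tRNA synthetases (ears-2), the respiratory chain (cox-5B), muscle (unc-60), sperm (spe-48), neurons (ins-39), mitochondrial ribosomal proteins (mrpl-23), germline (syp-4) and cuticle collagens (col-185), with adjusted p from 0.671 to 1 in the exact test. Without replicate 1 the respiratory chain passed (odds ratio 6.98, exact test, adjusted p = 0.0473) and no intestinal gene had a summit (odds ratio 0). The peaks assigned to mrpl-23, syp-4 and col-185 lay at a snoRNA, an snRNA and a tRNA gene. RNA polymerase I and III machinery had 0 of 14 and the proteasome 0 of 33 (exact test, adjusted p = 1 for both).

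Peaks were unevenly spread over chromosomes. X held 149 of 532 nuclear peaks (28.0%, exact 95% interval 24.2 to 32.0%) against 17.7% of nuclear length (exact binomial test, adjusted p = 1.1e-08), and V held 50 (9.40%, interval 7.06 to 12.2%) against 20.9% (adjusted p = 1.0e-11). Chromosomes I, II, III and IV did not pass, with ratios to length of 1.04, 1.05, 1.22 and 0.819. The central 50% of the autosomes held 222 of 383 autosomal peaks (57.96%, interval 52.8 to 62.96%; two-sided exact p = 0.0021), but with protein-coding genes as the expectation this was not called (ratio 1.04, exact p = 0.382). Without replicate 1, III (ratio 1.29, exact test, adjusted p = 0.0194) and IV (0.777, adjusted p = 0.0283) passed. With peaks near tRNA, snoRNA, snRNA and rRNA genes left out, a setting chosen after seeing the data, X was no longer called (ratio 1.22, exact test, adjusted p = 0.171). In that setting III passed (1.68, exact test, adjusted p = 8.2e-05) and the central 50% of autosomes did not (1.13, exact p = 0.0594).

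**Figure D3:**
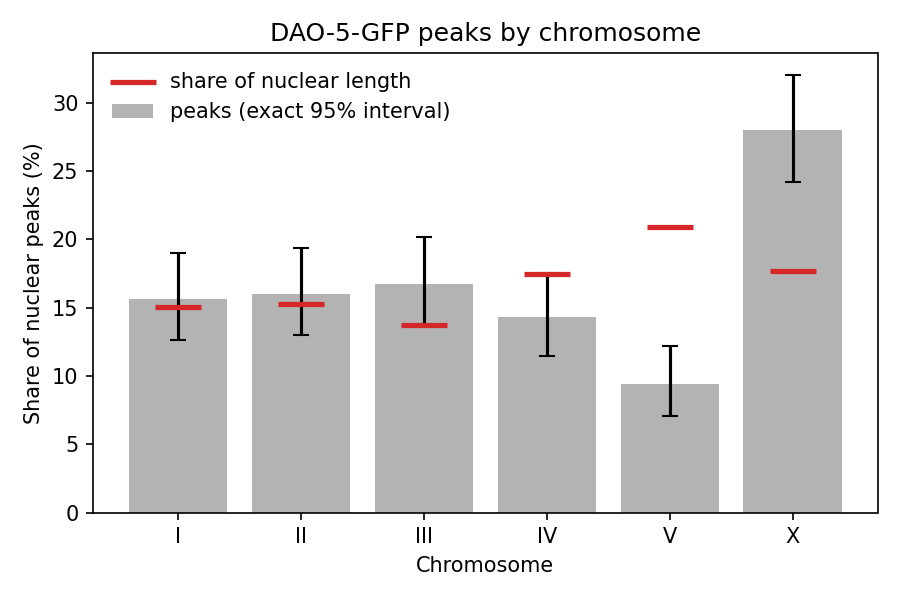
Share of the 532 nuclear peaks on each chromosome (bars, percent, with exact 95% intervals as error bars) and share of nuclear length (red marks). X stands above its length share at 28.0% and V below at 9.40%.

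Peaks in promoters had lower signal than the rest of the list, which included the 17 mitochondrial peaks (median 594.2). Promoter peaks here include those near small RNA genes, and the 139 away from such genes had a median of 61.1. The median was 62.4 for 199 promoter peaks and 68.2 for 350 others, a difference of -5.82 (two-sided permutation test, p = 0.0040). With nuclear peaks only, added after seeing the data, it was -3.45 and did not pass (permutation test, p = 0.0588). In the replicate lists alone it was -1.74 without replicate 1 (permutation p = 0.0722) and -1.06 without replicate 2 (permutation p = 0.412). Those differences are on a lower scale, since the median signal was 11.5 in the replicate 1 list and 10.95 in the replicate 2 list against 21.3 in the pooled list.

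Sequence at the summits was rich in G and C, at 49.2% within 50 bp against 36.1% in windows 500 bp away, a difference of 13.1 percentage points (SD of differences 11.7, n = 549 pairs, permutation p = 1e-05, the smallest possible). The core of the tRNA B box, GTTCGA, was present at 16.9% of summits and 3.46% of control windows (exact McNemar test, adjusted p = 1.9e-13). The GA repeat GAGAGA was at 17.7% against 5.83% (exact test, adjusted p = 4.4e-10), a difference of 11.8 points that was 6.93 among the 274 strongest peaks and 23.1 with 100 bp to each side. The GC box GGGCGG was at 8.74% against 1.46% (exact test, adjusted p = 6.6e-08). The splice-site control TTTCAG was at 4.92% against 18.9%, a difference of -14.03 percentage points that was -8.56 without replicate 2, and the A tract AAAAAA at 17.3% against 37.3%, so controls for composition differed between the windows as well. The E-box CACGTG (2.368% against 1.821%) and the GATA core TGATAA (6.38% against 9.84%) did not pass. TGATAA, with a difference of -3.46 points, passed in 4 other settings by the exact test: without replicate 2 (-4.92, adjusted p = 0.0042), among the 274 strongest peaks (-7.30, adjusted p = 0.0017), with 100 bp to each side (-5.10, adjusted p = 0.026) and with controls 1000 bp away (-4.92, adjusted p = 0.0065). Without replicate 1 it did not (-1.64, exact test, adjusted p = 0.407). Without peaks near small RNA genes the difference in GTTCGA fell to 2.68 percentage points and was no longer called (exact test, adjusted p = 0.177).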

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

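The tests of shared 30-base stretches, of identical tRNA copies and of tRNA genes on X against autosomes were set before their results were seen; the other tests on X, mitochondrial DNA and transcription level were chosen after, as were the comparison of tRNA genes with and without a repeated stretch and the share over tRNA copies without a thresholded peak.

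Signal appeared on mitochondrial DNA, outside the nuclear places the design asked about: 17 of the 549 thresholded peaks lay there. All 17 were among the 25 strongest, led by peaks at ND5 (signal 2372) and CYTB (1684), and the replicate lists held 20 and 18 such peaks. The thresholded ones covered 40.9% of the 13794 bp. Mitochondrial DNA is present in many copies per cell, and copies not balanced by the control may give such peaks. Coverage by peaks cannot separate this from binding, because depth of the immunoprecipitated and control reads was not analysed here, and no biological explanation was tested.

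Peaks at tRNA and snoRNA genes might come from reads shared between copies. For snoRNA this was argued against: 59 peaks lay only near snoRNA genes with no repeated stretch of 30 bases, against 1.38 in circular shifts. For tRNA it stays open. Only 20 tRNA genes lacked a repeated stretch, 1 of them (5%) had a peak against 203 of 592 others (34.3%; Fisher's exact p = 0.0062), and 0 peaks lay only near such genes, where shifts gave 0.086. In 48 families of identical tRNA genes with a thresholded peak, 9.48% of 443 copies lacked any pooled peak, which met the bound of under 10% set for reads spread evenly over copies. The support is weak: the 172 copies with a thresholded peak cannot lack a pooled one, and of the other 271, for which no bound was set, 15.5% lacked one. Recovery of highly transcribed genes by any precipitation cannot be told apart from binding, since an untagged strain was not analysed here; 11.5% of ribosomal protein genes had a summit.

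For the excess on X 2 candidate explanations were examined, and neither was settled. Of peaks near tRNA, snoRNA, snRNA or rRNA genes 35.2% lay on X, and of other nuclear peaks 21.6% (exact 95% interval 16.97 to 26.9%; Fisher's exact p = 6.8e-04), with 276 of 612 tRNA genes on X. The call for X ended without the former, as the ratio to length fell from 1.58 to 1.22. Peaks near those genes lay more often on X, so leaving them out had to lower the ratio and left fewer peaks to test. The lost call therefore does not bear on the cause. Whether tRNA genes on X have a peak more often stays open, at 37.3% against 30.1% on autosomes (Fisher's exact p = 0.0702). Among the 61 other X peaks, 13 (21.3%) held the dosage compensation motif TCGCGCAGGGAG with at most 2 mismatches within 200 bp. On autosomes 6 of 221 did (2.71%, Fisher's exact p = 6.9e-06). This met a criterion for the motif that was written after the peaks had been seen and that does not measure the excess. The interval for the X share of the other peaks holds the 17.7% of length. Whether they leave an excess for the motif to account for therefore stays open.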

How the results depend on the processing

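Settings without peaks near small RNA genes, with nuclear peaks only or with mitochondrial peaks included were chosen after seeing the data. Of 284 alternative values for 42 results with a test, 238 did not reverse direction and kept the call or the lack of one. Values of results that were called in no setting count among them. Another 20 concerned counts of peaks and loci, which were not tested. Replicate matching (42.5 to 55.1%), promoter share (1.43 to 2.78-fold), V and GC content kept direction and call in every setting run. So did the tRNA, snoRNA, snRNA and spliced leader excess and the ribosomal protein list (odds ratio 8.48 to 16.01, and 19.4-fold over circular shifts). Over all settings the excess ran from 23.2 to 94.2-fold for tRNA, 17.4 to 63.5-fold for snoRNA, 7.92 to 33.7-fold for snRNA and 15.1 to 52.6-fold for spliced leader genes. For the rest the cause was not tested. The ce10 chromosome test and ce10 ranks at dao-5 and rRNA genes were not run, since ce10 lengths and annotation were not used here, and ce10 replicate shifts ran over the span of the listed peaks. No paired analysis was possible because there was 1 group. Depth is unknown, so its limits were not measured.

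With protein-coding genes as the expectation, the ratios were 0.926 on II, 1.26 on III (now called) and 1.04 in the central 50% of autosomes (not called). Without peaks near small RNA genes they were 1.68 on III (called), 1.22 on X and 1.13 in the central 50% (neither called), GTTCGA differed by 2.68 percentage points (not called), and the odds ratios of mitochondrial ribosomal proteins and germline genes fell to 0. Among the 274 strongest peaks the excess was 1.67-fold for miRNA, 0.431-fold for piRNA, and the odds ratio 3.06 for chaperones and 0.135 for chemoreceptors, all no longer called; histones and intestine went to 0, collagens to 1.02 and neurons to 1.13, none called, and TGATAA differed by -7.30 (called). With overlap only miRNA was at 4.22-fold, and within 1000 bp at 2.52-fold with piRNA at 0.795-fold, none called. In the 500 bp window mitochondrial ribosomal proteins went to 0. In the 2000 bp window histones (3.79) and intestine (9.50) were called, proteasome (3.26) and collagens (1.15) turned without a call, and promoter signal differed by -2.19, no longer called. Among genes with a start of their own, mitochondrial ribosomal proteins and nucleolar genes went to 0. With circular shifts intestine was called (15.5-fold) and chemoreceptors were not (0.196-fold). With nuclear peaks only, signal differed by -3.45, not called. With 100 bp windows TGATAA differed by -5.10 (called) and CACGTG by -0.182 (not called), and with controls 1000 bp away TGATAA by -4.92 (called). Within 1000 bp, 1 rRNA gene had a replicate 2 peak.

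Leaving out each replicate in turn, the ratios ran from 1.22 to 1.29 on III and 0.777 to 0.800 on IV, the excess from 3.45 to 7.41-fold for miRNA and 0.411 to 0.606-fold for piRNA, and the odds ratios from 0 to 2.60 for the proteasome, 2.30 to 6.98 for the respiratory chain, 0 to 1.90 for germline genes, 0 to 4.87 for intestine, 6.22 to 7.54 for chaperones and 0.123 to 0.195 for chemoreceptors, with chaperones and chemoreceptors called each time. They ran from 1.23 to 3.64 for histones, 2.92 to 5.76 for nucleolar genes, 4.28 to 4.51 for translation factors, 2.68 to 5.87 for synthetases, 1.25 to 2.42 for mitochondrial ribosomal proteins and 0.461 to 0.981 for collagens, none called. Promoter signal differed by -1.74 to -1.06, on the lower scale of the replicate lists, and TGATAA by -4.92 to -1.64.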

Other observations

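All values and tests here were chosen after the peak positions had been seen, except the test of snoRNA location.

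Some other small RNA genes transcribed by RNA polymerase III had peaks, in families picked after the peaks were seen and not tested. These were 3 of 5 signal recognition particle RNA genes (srpr-1.2, srpr-2.1 and srpr-2.2), the RNase P RNA gene rpr-1 and the RNase MRP RNA gene mrpr-1. None of the 16 genes of 5S rRNA, which the same polymerase transcribes, had a thresholded peak. Whether reads from repeated genes such as rDNA were kept is unknown, so that absence does not measure a lack of binding. Shares of tRNA genes with a peak were 61.5% for cysteine (8 of 13), 45.5% for glycine (25 of 55), 16.7% for tryptophan (2 of 12) and 0 of 1 for selenocysteine, and differences between isotypes were not tested. At tRNA genes the median summit lay 12 bp past the start (quartiles -11.5 and 45.5, 143 peaks near 1 tRNA gene). At snoRNA genes the median summit lay upstream, at -31.5 bp (quartiles -58.2 and 3, 64 peaks). Summits lay upstream of the start for 73.4% of these snoRNA peaks and 35.7% of these tRNA peaks.

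The motif of dosage compensation sites was searched for near X peaks away from small RNA genes, and no map of such sites was used. With at most 1 mismatch it was near 10 of 61 such X peaks, 0 of 221 autosomal ones, 1 of 88 X peaks near small RNA genes and 2 of 2000 random X positions. The strongest was at 11094012 to 11094441 on X (signal 147.8), 3959 bp from the nearest gene start. With at most 2 mismatches, the replicate 1 list alone gave 12 of 66 X peaks against 6 of 261 autosomal ones and replicate 2 gave 13 of 49 against 6 of 231. Without motif-bearing peaks, X held 48 of 263 (18.3%) of these peaks, against 17.7% of length and 21.6% with them, which was not called. Since the motif was more frequent on X, leaving out its peaks had to lower the X share. The drop therefore does not bear on the cause.

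It was predicted that snoRNA genes outside protein-coding genes have a peak more often than those inside, where any overlap counted as inside. A peak was near 27 of 127 outside (21.3%) and 38 of 219 inside (17.4%). The difference did not pass (Fisher's exact p = 0.393), which leaves it open. Location does not show whether a snoRNA gene has a start of its own, so no conclusion on that is drawn.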
